A study of Mus musculus with 4 samples.

How the data were processed

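The data are expression profiles of E14 mouse embryonic stem cells, a line from an inbred mouse strain, measured on Affymetrix MoGene 1.0 ST arrays, with 2 arrays of control cells and 2 of cells with Kdm2b knocked down. Per the labels' protocols, the cells grew on gelatin in medium with 15% serum and 1000 units/ml of leukemia inhibitory factor. They were transduced with lentiviral vectors at 10 MOI, and puromycin at 2 µg/ml was added 48 h later to select transduced cells. Total RNA was labelled with biotin. Arrays were assigned to groups from the sample titles, which also give the replicate numbers. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

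The deposited table holds log2 expression per probe set for 35557 probe sets on each array, with 2 decimals. The authors used Affymetrix Expression Console, per the submitters' processing notes; its version, the background step and the summary method are not given in the sources used here. That the scale is log2 was read from the values, which run from 3.12 to 14.74. The values are not centred per gene, and the medians over all probe sets were 8.49 and 8.51 on the control arrays and 8.55 and 8.53 on the knockdown arrays. How the authors scaled the arrays to each other remains unknown. The number of arrays limits the precision.

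Probe sets were named through the platform annotation. Of the 35557 probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had no entry. Of the 21789, 21698 matched the RefSeq table of assembly GRCm38.p6 by Entrez ID, which changed 0 symbols, and 91 kept the annotation's symbol. The RefSeq table was used only for names and for which genes neighbour each other. Genes were named only from probe sets with 1 symbol. Where a gene had several probe sets (999 genes), the one with the highest mean over all 4 arrays was used, which gave 19938 genes. Of the 115 genes past the threshold that had a further probe set, 8 had one whose change went the opposite way.

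Knockdown and control were compared with limma 3.58.1 in R 4.3.3 on the log2 values as deposited (lmFit and eBayes with the default prior, group as the only term, two-sided, Benjamini-Hochberg adjustment over all 19938 genes). Genes with an adjusted p under 0.05 are called higher or lower after knockdown. Standard errors (SE) are limma's moderated ones, with a prior of 3.9 degrees of freedom, and SD is the standard deviation within a group. The design, 23 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The lists hold 484 entries, of which 438 were measured; 1 entry, Skp1a, was matched through a synonym, to Skp1. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, with adjustment over the 23 lists, and again with a correlation estimated from the arrays. fry tested each list without reference to other genes. The median of each list was also set against 10000 random lists matched on mean level in 20 bins.

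The text names Kdm2b, the 12 genes with the largest change in each direction among those past the threshold whose arrays were separated between the groups, and up to 4 called members of each list, or 2 as values where none was called. Clone names, predicted genes, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were left out of the top genes. Pou5f1, Sox2, Nanog, Gata4, Gata6, Fgf5, Cdx2, Cdkn2a and Cdkn2b are always given. The rule also listed the gene T, which is not analysed here. Genes named outside the rule were chosen after their values were seen: Ring1, Tcl1, Sox11, Rhox6, Asz1, Pdgfra, 9330159F19Rik and the lysosomal, folliculin-axis and Y-linked genes of the closing section.

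The procedure was tested on simulated data for the comparison of knockdown with control over 19938 genes. Of 50 genes simulated at each fold, it recovered 3 at 1.25-fold, 33 at 1.5-fold, 49 at 2-fold and 50 at 3-fold, and it called 11 of 19738 unchanged genes. In a further simulation with 3000 changed genes it called 2790 genes, of which 127 were unchanged. camera called 20 of 20 lists shifted by 0.25 and 1 of 100 lists that were not shifted. In these simulations the noise of each gene was drawn independently, so list members were uncorrelated. Correlations estimated from the arrays ran from -0.037 (ectoderm and neural markers) to 0.53 (cholesterol synthesis). The 1 of 100 is therefore no false-call rate for lists with correlated members.

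The alternatives were the replicate number as a block, leaving out each array in turn, quantile normalization, centring each array on its median, a filter on dim genes (mean log2 value above 8.52), every probe set with 1 symbol, every probe set of the table, the mean of a gene's probe sets, an intensity trend or a robust prior in eBayes, an adjusted p under 0.1, limma's treat against a 1.5-fold change, a fold of at least 1.5 in addition to the adjusted p, and a fold of at least 2 with separated groups and no test. Probe sets with several symbols or none entered only the test of the whole table and tests of their own.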

Results

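Gene expression was profiled on 4 arrays of E14 mouse embryonic stem cells kept in leukemia inhibitory factor, 2 from control cells and 2 from cells in which Kdm2b was knocked down. Kdm2b is a histone demethylase with a zinc finger that binds unmethylated CpG-rich DNA, and it is a subunit of a variant of Polycomb repressive complex 1 (PRC1). The series asks whether Kdm2b keeps these cells in the stem cell state by bringing PRC1 to the CpG islands of lineage genes, and the comparison of knockdown with control cells gives the expression side of that question. The median log2 value over all probe sets was 8.49 to 8.55 on the 4 arrays. Replicate arrays correlated with r = 0.9963 in control and 0.9966 in knockdown cells across probe sets, and arrays of different groups with r = 0.9922 to 0.9936. The leading principal component held 76.8% of the variance across the 19938 genes tested.

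Kdm2b itself, measured by 1 probe set, was lower in both knockdown arrays. Its log2 expression was 10.74 and 10.64 in control cells (10.69 ± 0.071, SD, n = 2) and 9.20 and 9.19 in knockdown cells (9.195 ± 0.0071, SD, n = 2). This is a log2 fold change of -1.50 (SE 0.066, adjusted p = 0.0039, limma), a level 2.82-fold lower than in control. The core stem cell factors did not pass the threshold. Pou5f1 had a log2 fold change of 0.08 (SE 0.064), Sox2 of -0.14 (SE 0.06) and Nanog of 0.14 (SE 0.061), with adjusted p-values of 0.451, 0.196 and 0.192. The value of Pou5f1 was 0.045 without knockdown replicate 2 and 0.04 with each array centred on its median. Kdm2b kept its direction when each array was left out in turn, with a log2 fold change from -1.55 to -1.45, but its adjusted p was then 0.258 without control replicate 1, 0.201 without control replicate 2, 0.24 without knockdown replicate 1 and 0.196 without knockdown replicate 2.

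**Figure D1:**
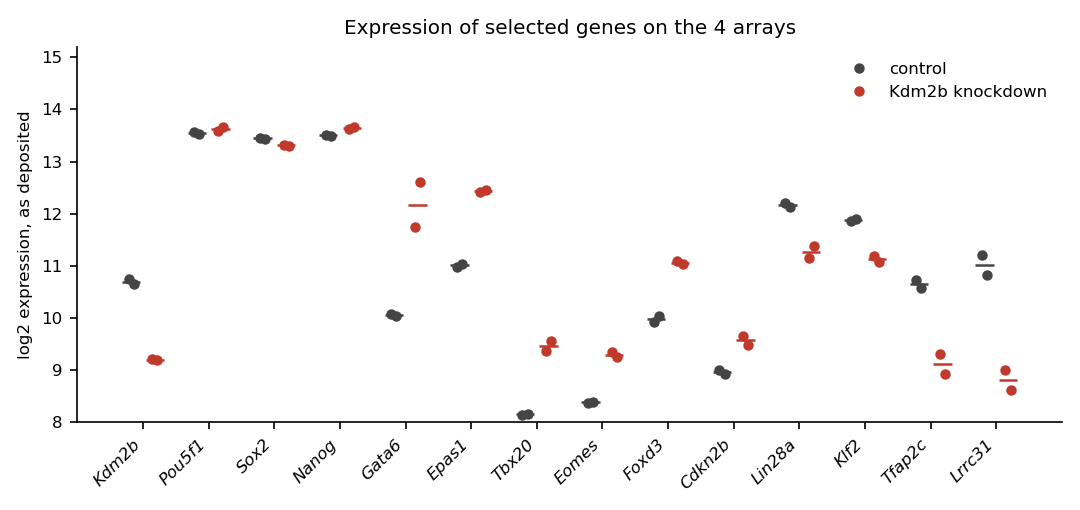
Log2 expression as deposited (y axis) of 14 genes on each of the 4 arrays; points are arrays, grey for control and red for Kdm2b knockdown, and the short lines are means of 2 arrays. Kdm2b lies near 10.69 in control and 9.20 in knockdown cells, Gata6 at 10.07 and 10.04 against 11.74 and 12.60, and Pou5f1 between 13.52 and 13.66 on the 4 arrays.

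After Kdm2b knockdown 997 genes were higher and 1434 lower, together 12.2% of the 19938 genes tested. For every gene named below as higher or lower, both knockdown arrays lay on the same side of both control arrays. Among the genes that rose most, Gata6, a regulator of primitive endoderm, rose by 2.12 on the log2 scale (SE 0.26, adjusted p = 0.0103, limma). Epas1, a hypoxia-inducible transcription factor, rose by 1.43 (SE 0.062), the homeobox gene Nkx2-9 by 1.35 (SE 0.22) and the T-box gene Tbx20 by 1.32 (SE 0.083). The other genes in this group of 12 were Soga3 (2.49), Usp17la (1.52), Tdpoz3 (1.44), Phlda1 (1.43), Cpe (1.41), Cbr3 (1.30), Apobec2 (1.30) and Mcc (1.29). 9330159F19Rik, which overlaps Soga3 in the RefSeq table and was chosen after its value was seen, rose by 2.60, so the changes of this pair may not be separate measurements.

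Among the genes that fell most were Lrrc31 (log2 fold change -2.20, SE 0.17, adjusted p = 0.0054, limma), Calml4 (-1.86, SE 0.12) and Tfap2c, a transcription factor of trophectoderm and germ cells (-1.54, SE 0.13). The others of the 12 were Nlrp4a (-1.76), Glod5 (-1.73), the Y-linked gene Zfy1 (-1.64), the mitochondrial acetyl-CoA synthetase Acss1 (-1.63), Obox6 (-1.55), the carbonic anhydrase Car6 (-1.52), Cyb5r2 (-1.51), Slfn9 (-1.44) and Rasgef1a (-1.43). Usp17la, Tdpoz3, Nlrp4a and Obox6 belong to families of closely related genes, so their values are uncertain where probes are shared, and Obox6 stood at -0.93 as the mean of its probe sets. These genes, Car6 and Zfy1 also lay at low levels, under the cut of the filter on dim genes. Their mean log2 values ran from 7.04 (Obox6) to 8.32 (Tdpoz3).

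Most of the changes were small. The median size of the log2 fold change among the genes past the threshold was 0.45, and 47 of the higher and 75 of the lower genes changed at least 2-fold. The arrays of the groups did not overlap for 58.8% of genes, where chance gives 33.3%. With any array left out limma called 0 genes in either direction, with 3495 to 4215 genes at an unadjusted p under 0.05 against 5941 with all 4 arrays. The fits without an array leave 1 residual degree of freedom, so the loss of calls cannot be laid to any single array. Their log2 fold changes correlated at 0.96 to 0.969 with those of all 4 arrays, with which they share arrays. In the test of every probe set of the table, named or not, limma also called 0 of 35557, with 7742 at an unadjusted p under 0.05.

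**Figure D2:**
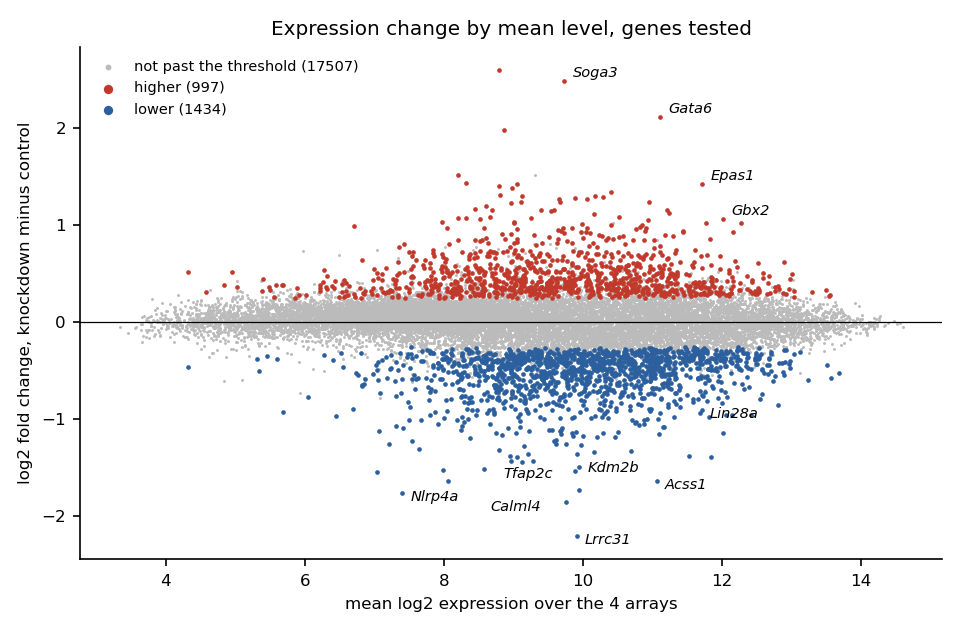
Log2 fold change, knockdown minus control (y axis), against mean log2 expression over the 4 arrays (x axis) for the 19938 genes tested; each point is a gene, red where higher (997), blue where lower (1434) and grey where not past the threshold. Gata6 lies at 2.12 and Lrrc31 at -2.20, and genes past the threshold occur at nearly all levels.

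The lineage genes that the series' title points to were examined with lists of markers. Markers of primitive and visceral endoderm, the extraembryonic lineage that Gata6 and Gata4 direct, rose as a set. Of 26 measured, 6 were higher, 0 lower and 20 neither (13 higher and 0 lower when adjusted over the list alone), and the median log2 fold change was 0.25. Besides Gata6, the adaptor gene Dab2 rose by 1.12 (SE 0.23), Srgn by 1.03 (SE 0.24) and the basement membrane collagen gene Col4a1 by 0.54 (SE 0.076). The value of Dab2 was 0.65 as the mean of its probe sets, and that of Srgn was 0.62 without control replicate 2. Gata4 had a log2 fold change of 0.51 (SE 0.17, adjusted p = 0.107, limma), and Pdgfra, chosen after its values were seen, 1.53 (SE 0.39, adjusted p = 0.0578). Without knockdown replicate 2 the value of Gata4 was 0.295 and that of Pdgfra 0.905. The list's shift had an adjusted p of 0.000185 in camera, and adjusted p = 0.69 with an estimated correlation. The same markers also differed between replicates of a group. Their median difference was 0.095 between the knockdown replicates and 0.095 between the control replicates, above the central 95% of random lists matched on level in each case.

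Primitive streak and mesoderm markers also rose as a set. Of 25 measured, 6 were higher, 0 lower and 19 neither (7 higher and 0 lower when adjusted over the list alone), with a median of 0.12. Tbx20, a cardiac T-box gene, Eomes (0.92, SE 0.067) and the signalling gene Bmp4 (0.61, SE 0.075) were among them. So was the endothelial receptor gene Kdr (0.36, SE 0.063). Kdr lay at a low level (mean log2 value 7.74), under the cut of the filter on dim genes. The set's adjusted p was 0.00754 in camera, adjusted p = 0.69 with an estimated correlation, and 0.125 without control replicate 2, where the median was 0.055. With each array centred on its median the list's median was 0.075 and the shift still passed (0.00434).

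Of 24 ectoderm and neural markers, 4 were higher, 1 lower and 19 neither (6 higher and 1 lower when adjusted over the list alone), and the median was 0.17. The intermediate filament gene Nes rose by 0.72 (SE 0.11), Neurog3 by 0.40 and Pou4f1 by 0.34. Neurog3 lay at a low level (mean log2 value 8.44), under the cut of the filter on dim genes. Sox11, chosen after its values were seen, rose by 0.32, while Pax6, a regulator of eye and brain development, fell by 0.80 (SE 0.076). The set's shift was upward (adjusted p = 0.00754 in camera, adjusted p = 0.69 with an estimated correlation), and its adjusted p was 0.0826 with dim genes removed. Hox genes lay at low levels (mean log2 value 7.82) and moved little. Of 37 measured, 1, Hoxa10, was higher (0.42, SE 0.06), 0 were lower and 36 neither (1 higher and 0 lower when adjusted over the list alone), and 31 had a positive log2 fold change, with a median of 0.11. Their upward shift had an adjusted p of 0.0369 in camera, adjusted p = 0.69 with an estimated correlation. It was not past the threshold after quantile normalization (median 0.0562, adjusted p = 0.252), with dim genes removed (median 0.0325, 0.87), without control replicate 2 (0.125) or without knockdown replicate 1 (0.0547), and with each array centred on its median the Hox median was 0.07 (0.0464).

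Trophectoderm markers went both ways. Of 18 measured, 2 were higher, 4 lower and 12 neither (2 higher and 4 lower when adjusted over the list alone), with a median of -0.04, and the set did not pass the threshold (adjusted p = 0.33, camera). The median was 0 without control replicate 1 and -0.07 without control replicate 2, -0.0934 after quantile normalization, -0.075 with each array centred on its median and -0.125 with dim genes removed. Tfap2c fell by 1.54, the homeobox gene Rhox9 by 1.13 (SE 0.14), Gata2 by 0.44 and Rhox6, chosen after its values were seen, by 0.33. The keratin gene Krt8 rose by 0.79 (SE 0.07) and Cdx2, a trophectoderm regulator, by 0.35 (SE 0.065). Cdx2 lay at a low level (mean log2 value 8.15), under the cut of the filter on dim genes.

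Among 24 pluripotency factors, 1 was higher, 4 lower and 19 neither (3 higher and 4 lower when adjusted over the list alone). Gbx2 rose by 1.07 (SE 0.11). Dppa3, a gene of naive stem cells and germ cells, fell by 0.99 (SE 0.095), the RNA-binding protein gene Lin28a by 0.90 (SE 0.09), Klf2 by 0.75 (SE 0.068) and Tcl1, chosen after its values were seen, by 0.37 (SE 0.064). Dppa3 had 2 probe sets, of which the brighter is given. Whether that probe set reads Dppa3 itself or a related gene was not examined, so its fall is uncertain. The probe set lay at a low level (mean log2 value 8.01), under the cut of the filter on dim genes. As a set the factors did not pass the threshold (median 0, and from -0.005 to 0.0475 with each array left out, adjusted p = 0.527, camera). Of 17 markers of primed epiblast, 3 were higher, 0 lower and 14 neither (5 higher and 2 lower when adjusted over the list alone). Foxd3 rose by 1.09 (SE 0.07), the cadherin gene Cdh2 by 0.46 and Sox4 by 0.38, and Fgf5 had a log2 fold change of 0.35 (SE 0.17, adjusted p = 0.238, limma), which was 0.09 without knockdown replicate 1 and 0.60 without knockdown replicate 2. The median of this list was 0.23, and its adjusted p of 0.0889 in camera did not pass the threshold. The median was 0.06 without control replicate 1 and 0.08 without knockdown replicate 1, and 0.345 without knockdown replicate 2, where the shift passed (0.0186), as it did with each array centred on its median (0.0436).

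Genes known from 2-cell-like cells, a rare state in stem cell cultures that resembles the early embryo, were higher as a set. Of 15 listed, only 7 were measured. Of these, 3 were higher, 0 lower and 4 neither (5 higher and 0 lower when adjusted over the list alone). All 7 had a positive log2 fold change, with a median of 0.60. The members past the threshold, Usp17la, Usp17lb (1.16, SE 0.2) and Usp17lc (0.88, SE 0.17), are near-identical deubiquitinase genes whose probes may not tell them apart. The shift had an adjusted p of 0.00477 in camera, adjusted p = 0.69 with an estimated correlation, and 0.0826 with dim genes removed. Without knockdown replicate 1 the median was 0.36, and the shift still passed (0.00702). Germline genes were mixed. Of 20 measured, 3 were higher, 2 lower and 15 neither (6 higher and 3 lower when adjusted over the list alone), with a median of 0.17 and an adjusted p of 0.267 in camera. The median was 0.225 without knockdown replicate 1, where the shift passed (0.0364), but 0.0525 without knockdown replicate 2 (0.957) and 0.0925 with dim genes removed. Dazl rose by 0.96 (SE 0.13), Syce1 by 0.59 and Asz1, chosen after its values were seen, by 0.48. Asz1 lay at a low level (mean log2 value 6.32), under the cut of the filter on dim genes. The synaptonemal complex gene Sycp3 fell by 1.14 (SE 0.11) and Smc1b by 0.51.

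Of 19 imprinted genes, 6 were higher, 1 lower and 12 neither (8 higher and 3 lower when adjusted over the list alone), with a median of 0.15 (adjusted p = 0.374, camera) that was 0.0912 after quantile normalization and 0.1 without control replicate 1 and without knockdown replicate 2. Cdkn1c, Mest (0.51) and Nnat (0.44) rose, and Impact fell by 0.96 (SE 0.074). Of 18 fibroblast and feeder markers, Twist1 was higher (0.43), Acta2 lower (-0.41) and 16 neither (1 higher and 1 lower when adjusted over the list alone). Their median was 0.06 (adjusted p = 0.896, camera), and 0.0206 after quantile normalization and 0.015 with each array centred on its median.

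The partners of Kdm2b in variant PRC1 that passed the threshold changed less than Kdm2b. Of 10 members measured, Kdm2b included, 3 were higher, 2 lower and 5 neither (3 higher and 2 lower when adjusted over the list alone), with a median of -0.01 (adjusted p = 0.892, camera) that ran from -0.0025 to 0.0075 with each array left out. Bcorl1 rose by 0.64 (SE 0.11), Bcor by 0.49 (SE 0.099) and Ring1, chosen after its values were seen, by 0.28 (SE 0.067), while Yaf2 fell by 0.31 (SE 0.06). Of 16 other PRC1 subunits 0 were higher, 3 lower and 13 neither (1 higher and 4 lower when adjusted over the list alone), namely Pcgf5 (-0.68, SE 0.11), Auts2 (-0.38) and Mga (-0.37). Of 11 PRC2 subunits 0 were higher, 2 lower and 9 neither (0 higher and 3 lower when adjusted over the list alone), namely Phf19 (-0.74, SE 0.084) and Ezh1 (-0.32). The medians were -0.11 and -0.09, and neither set passed the threshold (adjusted p = 0.0768 for each, camera). The other PRC1 subunits passed without control replicate 2 (0.0399), the PRC2 subunits without knockdown replicate 2 (0.0422), and both with an intensity trend in the prior (0.0437 and 0.046). Of 18 other JmjC and CxxC factors, Kdm6b, an H3K27 demethylase, was higher (0.53, SE 0.061), 0 were lower and 17 neither (1 higher and 0 lower when adjusted over the list alone), with a median of -0.01 (adjusted p = 0.606, camera) that was 0.0275 without knockdown replicate 2 and -0.0375 without knockdown replicate 1.

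Of 6 CDK inhibitors measured, 3 were higher, 0 lower and 3 neither (4 higher and 0 lower when adjusted over the list alone). Cdkn2b rose by 0.61 (SE 0.08), Cdkn1c by 0.58 (SE 0.09) and Cdkn2a by 0.48 (SE 0.062), and as a set (median 0.34) they did not pass the threshold (adjusted p = 0.0768, camera), but they did with each array centred on its median (median 0.295, adjusted p = 0.0436). Of 19 p53 targets measured, 4 were higher, 0 lower and 15 neither (9 higher and 2 lower when adjusted over the list alone), with a median of 0.28. Bax and Cdkn1a, the latter also on the list of CDK inhibitors, were listed but were not among the genes measured. Plk2, a stress-responsive kinase, rose by 1.27 (SE 0.24), Perp by 1.245 (SE 0.14) and the pro-apoptotic Pmaip1 and Phlda3 by 0.67 each. The set shifted upward (adjusted p = 0.0139 in camera, adjusted p = 0.69 with an estimated correlation). It was not past the threshold without control replicate 1 (0.116), control replicate 2 (0.125) or knockdown replicate 1 (0.0547, with a median of 0.16). Of 23 cell proliferation genes, 2 were higher, 1 lower and 20 neither (2 higher and 1 lower when adjusted over the list alone). Myc rose by 1.03 (SE 0.14) and Ccnd1 by 0.38, E2f1 fell by 0.35, and the median was -0.01 (adjusted p = 0.606, camera), or 0.02 without knockdown replicate 1, 0 without control replicate 2 and -0.02 without either of the other arrays.

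Genes of the integrated stress and unfolded protein responses fell as a set. Of 16 measured, 0 were higher, 3 lower and 13 neither (2 higher and 4 lower when adjusted over the list alone), with a median of -0.28. Ddit4, an inhibitor of mTOR signalling, fell by 0.55 (SE 0.061), the serine synthesis gene Phgdh by 0.48 and the chaperone gene Dnajb9 by 0.36. The adjusted p was 0.00767 in camera, adjusted p = 0.69 with an estimated correlation. It was 0.0904 with dim genes removed, 0.109 without control replicate 1 and 0.0547 without knockdown replicate 1, where the median was -0.158. Glycolysis and hypoxia genes were also lower as a set, with 0 of 18 higher, 2 lower and 16 neither (0 higher and 4 lower when adjusted over the list alone) and a median of -0.14. The glycolytic enzyme genes Tpi1 (-0.40, SE 0.059) and Pfkl (-0.30, SE 0.069) fell. The adjusted p was 0.0135 in camera, adjusted p = 0.69 with an estimated correlation. It was 0.0826 with dim genes removed, 0.258 without control replicate 2 and 0.0547 without knockdown replicate 1, where the median was -0.065.

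The remaining lists had 1 gene or none past the threshold. Of 20 interferon response genes, 0 were higher, 1 (Stat2, -0.68, SE 0.1) lower and 19 neither (0 higher and 1 lower when adjusted over the list alone), with a median of 0.03 (adjusted p = 0.896, camera) that ran from 0.0175 to 0.05 with each array left out and was -0.015 with each array centred on its median and -0.1 with dim genes removed. No cholesterol synthesis gene passed the limma threshold (0 of 16, and 0 when adjusted over the list alone), with Hmgcs1 at 0.43 (SE 0.15) and Insig1 at -0.28 (SE 0.11) as the widest values and a median of 0.06 (adjusted p = 0.606, camera). The cholesterol median ran from 0.0125 without control replicate 1 to 0.1 without control replicate 2, and it was 0.0275 without knockdown replicate 1. Hmgcs1 was at 0.245 without control replicate 1 and 0.28 without knockdown replicate 1, and Insig1 at -0.185 without control replicate 2 and -0.155 without knockdown replicate 2. Ribosomal protein genes also had 0 of 30 past the limma threshold, and 0 when adjusted over the list alone. Rps27l stood at -0.16 (SE 0.068) and Rpl30 at 0.14 (SE 0.068), and the median of -0.05 did not pass the threshold (adjusted p = 0.0889, camera), but the list passed without control replicate 1 (0.0368), without knockdown replicate 2 (0.0107) and with an intensity trend in the prior (0.0181). Its median was -0.09 with each array centred on its median, Rps27l was at -0.105 without knockdown replicate 1, and Rpl30 at 0.085 without control replicate 1.

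**Figure D3:**
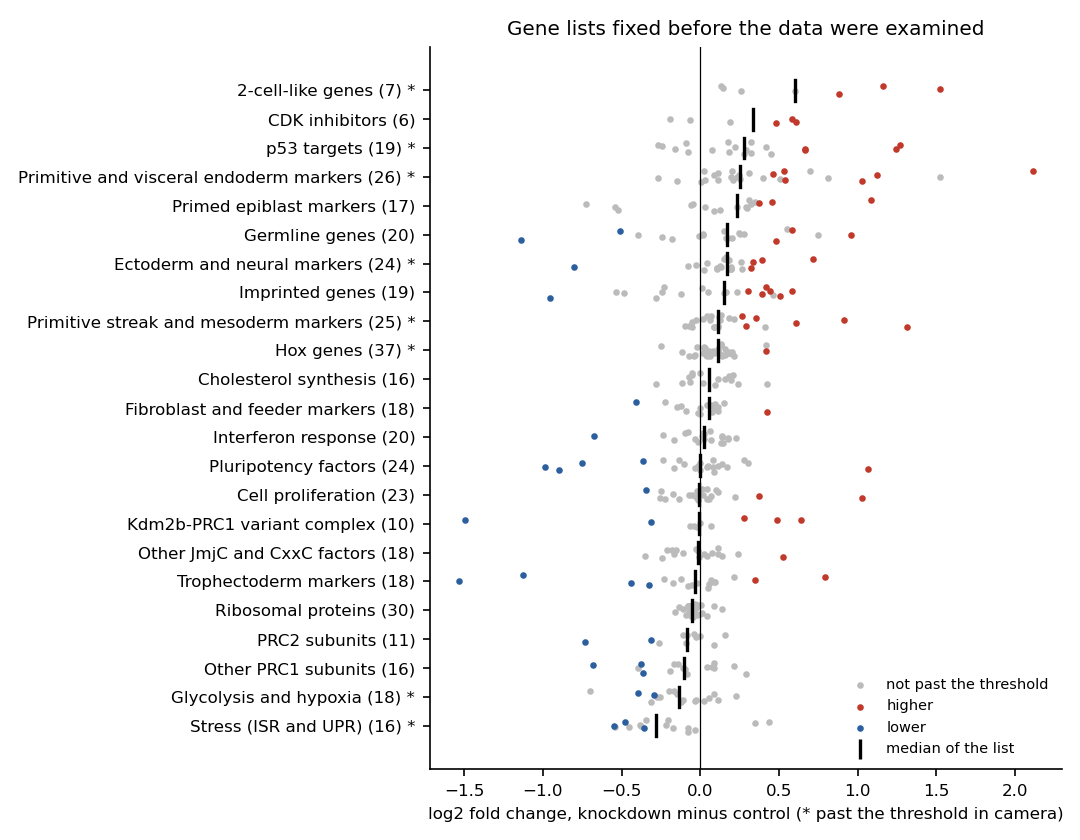
Log2 fold change, knockdown minus control (x axis), of the measured members of the 23 gene lists (y axis, number measured in brackets); points are genes, red where higher, blue where lower and grey where not past the threshold, black ticks are medians, and asterisks mark the 8 lists past the threshold in camera with the preset correlation. Medians run from -0.28 for the stress list to 0.60 for the 2-cell-like list.

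In all, 8 of the 23 lists passed in camera with the preset correlation, 6 upward and 2 downward. With the correlation estimated from the arrays 0 lists passed in camera and 0 were at an unadjusted p under 0.05, and 0 passed in fry.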

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

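All tests here were planned except the lysosomal subset, chosen after seeing the data. Under quantile normalization, median centring, the dim filter, probe set means, every probe set with 1 symbol, and a trend or robust prior, calls ran from 841 to 1109 higher and 1438 to 1866 lower, and Kdm2b, not read out for every probe set with 1 symbol, stayed past the threshold from -1.54 to -1.49. The robust prior gave no list test.

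With the replicate number as a block limma called 0 genes higher and 0 lower (5411 at an unadjusted p under 0.05), Kdm2b stayed at -1.50 (adjusted p = 0.127) and 8 lists passed, with p53 targets lost (adjusted p = 0.0911) and ribosomal proteins gained (0.0272); same-numbered arrays deviated with a correlation of 0.095 over genes, and 1 residual degree of freedom remained. Without any 1 array limma called 0 higher and 0 lower; a lone array is assumed to vary like the other group. Kdm2b then ranged from -1.55 to -1.45 and the number of lists past the threshold from 5 to 11.

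Every probe set of the table gave 0 higher and 0 lower. Unannotated probe sets varied more within groups (median SD 0.113 against 0.068), and the prior degrees of freedom were 2.29 against 3.9. Tested on their own, the 12147 unannotated probe sets gave 0 calls. The 1621 with several symbols also gave 0, with 348 at an unadjusted p under 0.05 in limma, although their median SD was only 0.0585. Spread within groups is therefore not the whole reason for the loss of calls. An adjusted p under 0.1 gave 1920 and 2236, treat 3 and 1, a fold of 1.5 added to the adjusted p 240 and 447, and a fold of 2 without a test 49 and 75, as these criteria are looser or stricter by construction.

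Against 8 lists past the threshold, 10 passed with median centring, 11 with the trend, 8 with probe set means, 7 with quantile normalization, 3 with the dim filter, 0 with an estimated correlation and 0 in fry. All named genes that were called kept their sign in every fit that measured them. List directions reversed only among lists not called. Under quantile normalization the medians were 0.00312 (Kdm2b-PRC1), 0.00719 (JmjC and CxxC), 0.00344 (interferon), 0.0206 (fibroblast) and 0.00875 (proliferation). With the dim filter they were -0.01 (Kdm2b-PRC1), 0 (pluripotency) and -0.1 (interferon), and in fry -0.0125 (JmjC and CxxC). Without 1 array the cholesterol median ranged from 0.0125 to 0.1 and the germline median from 0.0525 to 0.25. The cause was not tested. Some medians kept their sign while the test turned. Signal over background was not analysed here.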

Other observations

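The tests in this part were chosen after the result was seen, except the brightness test of lysosomal genes, whose prediction was written before its result. The lists of lysosomal, folliculin-axis and Y-linked genes were written after the table had been seen, and 37 of the lysosomal and all of the folliculin-axis and Y-linked members had been looked up by then.

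Some genes of the lysosome were lower after Kdm2b knockdown. Of 82 measured, 29 were lower, 2 higher and 51 neither by limma over all genes, with a median log2 fold change of -0.22. The 37 members already looked up hold 19 of the 29 and have a median of -0.42, and for the 82 camera with an estimated correlation gave p = 0.21. The hydrolase genes Hexa (-1.38, SE 0.19), Idua (-1.27, SE 0.088) and Fuca2 (-1.09, SE 0.13), the transporter genes Ctns (-1.01, SE 0.14) and Slc17a5 (-0.87, SE 0.061), Cln6 (-0.95, SE 0.065) and the membrane protein gene Lamp2 (-0.84, SE 0.083) were among those that fell. Of the 45 members not looked up before, 10 were lower, 2 higher and 33 neither, and the median was -0.15. It was -0.09 without control replicate 1, -0.19 without control replicate 2, -0.175 without knockdown replicate 1 and -0.105 without knockdown replicate 2. Litaf (-0.67) and Sort1 (-0.64) fell and Hyal2 (0.44) and Laptm5 (0.50) rose among them. For these 45, camera gave p = 0.000206 with the preset correlation and p = 0.24 with an estimated correlation, each unadjusted. In the folliculin and Rag GTPase axis, which controls the lysosomal regulator TFE3, Fnip1 (-1.08, SE 0.11) and Rragd (-0.98, SE 0.14) fell; 6 of the 8 genes listed were lower, but all 8 were listed with their values known, so the count tests nothing. Tfe3 (-0.12, SE 0.065, and -0.07 without knockdown replicate 2) and Tfeb (0.20, SE 0.062) did not pass the threshold.

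A shift of probe sets by brightness does not account for the lysosomal pattern, since the median of the 45 members not looked up before lay at percentile 0.01 of 10000 random lists matched on level, and no higher than 0.52 with any array left out. A difference in culture state between the knockdown and control dishes, such as density or nutrient supply, stays open, since it goes with the groups. The stress list also moved downward (median -0.283), but its adjusted p was 0.69 in camera with an estimated correlation. Most lysosomal genes were higher on control replicate 1 than on control replicate 2, such as Hexa (12.49 and 11.94) and Ctns (11.54 and 11.23). Gusb (9.80 and 9.97) was among those that went the other way. Lysosomal genes thus differed between the 2 control arrays too, which was not set against random lists. A response of the cells to the loss of Kdm2b may also have lowered these genes, as a hypothesis that was not tested. These last explanations cannot be told apart here, because the knockdown and control dishes are the only ones measured.

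The primitive endoderm markers lay at percentile 100 of random lists matched on level, so their rise is not a shift by brightness. They also moved together between the knockdown replicates, where their median difference lay at percentile 100, and between the control replicates, at percentile 99.9. The members behind these differences were only partly the same. Gata6 was nearly equal on the control arrays (10.07 and 10.04) but not on the knockdown arrays (11.74 and 12.60). Dab2 differed between the control arrays (9.97 and 9.23) more than between the knockdown arrays (10.67 and 10.77). Pdgfra differed in both groups (8.76 and 8.33, 9.45 and 10.69). A share of endoderm-like cells that varies between samples could give part of these differences, though the labels do not say whether replicates came from separate cultures. The median differences within groups, 0.095 in each, were smaller than the 0.25 between groups, and with 2 arrays per group a chance difference in that share and a rise caused by the knockdown both stay open.

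For the Hox genes the median lay at percentile 98.8 of random lists matched on level, so few such lists reached it. Brightness as the main source of their small upward shift is not excluded, since the shift depended on the processing. Random lists had a median of 0.055 against 0.11 for the Hox genes, so part of the Hox value may be shared by other dim genes. After quantile normalization the Hox median was 0.0562 and its test did not pass (adjusted p = 0.252, camera). With dim genes removed the Hox median was 0.0325 (adjusted p = 0.87, camera).

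The 4 arrays can be split into pairs in 3 ways. With limma the real split called 2431 genes and the highest of the others 0 (180 and 81 at an unadjusted p under 0.05), so 1 of the 3 splits, the real one, reached that count. With 3 splits a share under 0.05 cannot be reached. Each other split puts 1 control and 1 knockdown array in each pair, so any group difference widens its spread within pairs. Its 0 calls therefore do not show what chance yields.

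Of 9 Y-linked genes, listed with their values known, 2 (Zfy1 and Uty) were lower, 0 higher and 7 neither by limma. Log2 fold changes were -1.64 (Zfy1), -0.52 (Uty), -0.35 (Uba1y), -0.23 (Eif2s3y), -0.17 (Zfy2) and 0 (Kdm5d). Sry (0.125), Srsy (0.085) and Usp9y (0.045) had positive values. Usp9y, Zfy2, Srsy and Kdm5d lay at low levels (mean log2 values 5.72, 5.745, 6.50 and 6.91). Eif2s3y (11.20), Uty (10.76), Uba1y (9.865) and Zfy1 (8.065), whose values were negative, lay higher, as did Sry (9.57). Adjacent genes were called in the same direction in 230 pairs of neighbours, against a mean of 153 in 10000 permutations of the calls (130 to 176 in the central 95%). Without overlapping genes and pairs of a shared family name the count was 179 against 118 (98 to 138), with a one-sided permutation p of 1e-04 in each case, the smallest these permutations can give. Calls were rarer among dim genes, with 16 higher and 6 lower of 1557 at a mean log2 value below 6. At 9 to 10 they were 238 and 389 of 2854. Whether neighbours share levels, and so calls, was not tested, so the excess is not read as regional regulation.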
